A study of Mus musculus with 2 samples.

How the data were processed

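Lineage-depleted bone marrow of C57BL/6 mice was measured in 1 WT and 1 Nat10 cKO library of droplet-based 3′ single-cell RNA sequencing. The count values used here are UMIs per gene and barcode as deposited, in a matrix for each library with 56748 genes, and every value was checked to be a whole number. Per the submitters' processing notes, reads were aligned to the mouse genome mm39 and UMIs counted by the authors with Cell Ranger 7.1.0. How barcodes were called cells is not given in the sources used here. The WT matrix held 15848 barcodes and the cKO matrix 13479, none with under 500 UMIs. Group membership came from the sample labels.

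Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, 12537 in the WT and 11239 in the cKO library. Scrublet, as built into scanpy 1.11.5, was run on each library with an expected share of 8%, and called 667 WT barcodes (5.32%) and 618 cKO barcodes (5.50%) doublets, which were removed. The 11870 WT cells left held 261747629 UMIs, and the 10621 cKO cells 253353004. Medians of 4902 and 5120 genes per cell were detected. Under 3000 UMIs were 24.9% of the kept WT and 16.8% of the kept cKO cells. In HSC/MPP-like cells Nat10 rested on 538 and 225 UMIs, which gives its log2 ratio an interval from −0.59 to −0.13.

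Both libraries were clustered together without integration. UMIs were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.5 were used (scanpy, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0). A cluster took the class with the most markers among its 10 leading genes, and between equals the class with the largest share of its markers detected. A marker counted as detected at a fold of at least 2 over the other cells and a mean of at least 0.2 scaled UMIs, and at least 3 detected markers were needed. Clusters of at least 200 cells whose leading genes held markers of 2 classes alike were split once, at resolution 0.5, and shallow clusters with no marker among the leading genes stayed unnamed. Marker lists for 18 classes were written before the data were examined, as were the gene lists, the named-gene rule, the filters and most alternatives. Of 48 clusters 42 were named, into 17 classes; no mature B cell cluster was named. The 6 unnamed clusters held 2807 WT and 1752 cKO cells, and 1 of them, with 210 and 264 cells, was left unnamed by a rule set after the clusters were seen. Unnamed cells stay in the denominator of every share. Names end in "-like" because no surface marker was measured.

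For gene ratios, UMIs were summed over all kept cells and over each of the 10 classes with at least 100 cells in both libraries, and scaled by total UMIs to CPM. The log2 ratio of cKO over WT was taken with 0.5 added to each sum. With 1 library per genotype no test between genotypes was made, and cells were not used as replicates. Intervals of 95% are exact Poisson intervals for sums, exact binomial intervals for shares and exact conditional binomial intervals for ratios of sums or shares. For list medians they are quantiles over Poisson redraws of the members' sums, and for quotients of share ratios normal intervals on the log scale. All cover counting error only (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). Named genes are the 10 highest and 10 lowest ratios in all kept and HSC/MPP-like cells and 5 at each end in the other classes, among genes with a mean of at least 20 CPM and at least 100 UMIs, along with genes fixed in advance and the 2 highest and 2 lowest members of each list. Unnamed gene models, immunoglobulin, T cell receptor, haemoglobin, mitochondrial and sex-linked genes were left out of the ranking. Genes that lead a cluster of the class itself were not reported as results at the ends of a ranking.

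Medians of 25 gene lists were taken over members with at least 50 UMIs in both libraries together and where at least 5 members were measured. The lists were ribosome biogenesis, cytosolic ribosomal proteins, translation factors, mitochondrial ribosomal proteins, oxidative phosphorylation, genes encoded in mitochondria, glycolysis, p53 targets, S phase, G2/M, MYC targets, integrated stress response, unfolded protein response, interferon response, inflammatory NF-kB targets, immediate early and heat shock, apoptosis regulators, cholesterol biosynthesis, HSC-associated, erythroid, megakaryocyte, myeloid granule, lymphoid, MHC class II and sex-linked genes. Each median was placed by percentile among 10000 random lists that took, for each member, 1 of the 100 genes nearest in mean CPM. Members of the list itself were not left out of these draws. Such a percentile describes these 2 libraries and is no test between genotypes. Random lists and genes compared with Nat10 that were matched on gene span too were chosen after seeing the data. Spans came from GENCODE vM21, in which 91.8% of the gene IDs were found. That annotation is of another genome build than the matrices, so no coordinates are given.

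The HSC gene-positive share counts cells with UMIs of at least 2 of 8 genes after thinning every cell to 2000 UMIs, and leaves out cells below that depth. Alternatives were a stricter filter (3000 UMIs, 1500 genes, 5% mitochondrial), all barcodes with at least 200 genes, doublets kept, Leiden resolutions 0.8 and 2.5, genes scaled within each library, variable genes without cell cycle, ribosomal protein and mitochondrial genes, and class by marker score. Others were denominators of progenitor classes or of named classes, TMM factors (edgeR 4.0.16) and median-of-ratios factors (DESeq2 1.42.0, R 4.3.3) used as scaling only, mean per-cell CPM, totals without haemoglobin, ribosomal protein and mitochondrial genes, and reweighting to WT class or cluster shares. Floors of none and 500 UMIs, an addition of 5 counts, 3 of the 8 HSC genes, no thinning and thinning to 4000 UMIs were also run. Cluster reweighting and the named-class denominator were chosen after seeing the data.

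The gene and list steps were tested on simulated data, with sums drawn as independent Poisson counts from the pooled means at the real totals. In each of 2 simulated comparisons, 100 of 100 genes set to a fold of 2 and 100 of 100 set to 0.5 came out on the right side. Intervals held the true value for 91 and 95 of them at HSC/MPP-like depth and for 96 and 94 at erythroid progenitor-like depth. A list raised in both comparisons lay at percentile 100, and 23 of 23 lists left alone lay in the central range. The simulated sums held no trend with gene span and no spread beyond counting, so percentiles were not checked against either. Figures were drawn with matplotlib 3.10.9. Differences between mice were not analysed here, because no label maps cells to mice.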

Results

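Lineage-depleted bone marrow cells of wild-type (WT) C57BL/6 mice and of mice with a conditional knockout (cKO) of Nat10 were measured by droplet-based single-cell RNA sequencing of 3′ tags. Nat10 encodes the enzyme that acetylates cytidine in RNA to N4-acetylcytidine (ac4C), and the series asks what this modification does in the maintenance and differentiation of haematopoietic stem cells. The series text names 5 WT or cKO mice, but no label maps a cell to a mouse. Each genotype had 1 library, so no difference below has a replicate check, and every interval covers counting error only. The WT library held 15848 barcodes with 288303275 unique molecular identifiers (UMIs, each counting 1 captured transcript) and a median of 8349.5 UMIs per barcode. The cKO library held 13479 barcodes with 271499717 UMIs and a median of 11675. After filtering, 11870 WT cells with a median of 18411.5 UMIs and 10621 cKO cells with a median of 21640 UMIs were kept.

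Nat10 itself was lower in the cKO library in 9 of the 10 cell classes measured, by less than a full loss. In all kept cells Nat10 stood at 47.1 CPM (counts scaled to the same total) in the WT library and 38.7 CPM in the cKO library, a log2 ratio of −0.28 (95% interval −0.32 to −0.24). Erythroid progenitor-like cells held the most Nat10, with 70.0 against 48.8 CPM and a log2 ratio of −0.52 (−0.57 to −0.47). In haematopoietic stem cell and multipotent progenitor-like (HSC/MPP-like) cells the values were 38.1 and 29.7 CPM, a log2 ratio of −0.36 (−0.59 to −0.13). Of 100 genes with a like CPM, 0 had a lower ratio than Nat10 in erythroid progenitor-like cells, 20 in HSC/MPP-like cells and 26 in all kept cells; with genes of like CPM and span these counts were 2, 26 and 12. Conventional dendritic-like cells gave a log2 ratio of −0.82 (−1.36 to −0.33), and stromal/endothelial-like cells, at 26.4 and 26.8 CPM, gave 0.02 (−0.54 to 0.60), which became −1.14 when every cell weighed alike. The ratio in erythroblast-like cells, −0.38, turned to 0.06 when every cell weighed alike. In all kept cells it was −0.19 after trimmed mean of M-values (TMM) scaling and −0.45 with the cKO classes reweighted to the WT class shares. Thumpd1, which encodes the adaptor that Nat10 uses on transfer RNA, had log2 ratios of 0.20 in all kept cells, 0.14 (−0.03 to 0.32) in HSC/MPP-like cells and 0.06 in erythroid progenitor-like cells, the last turning to −0.03 with the WT mix of clusters. The labels do not name the deleted part of Nat10, and 3′ tags outside it would check nothing, so these levels do not test the knockout.

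**Figure D1:**
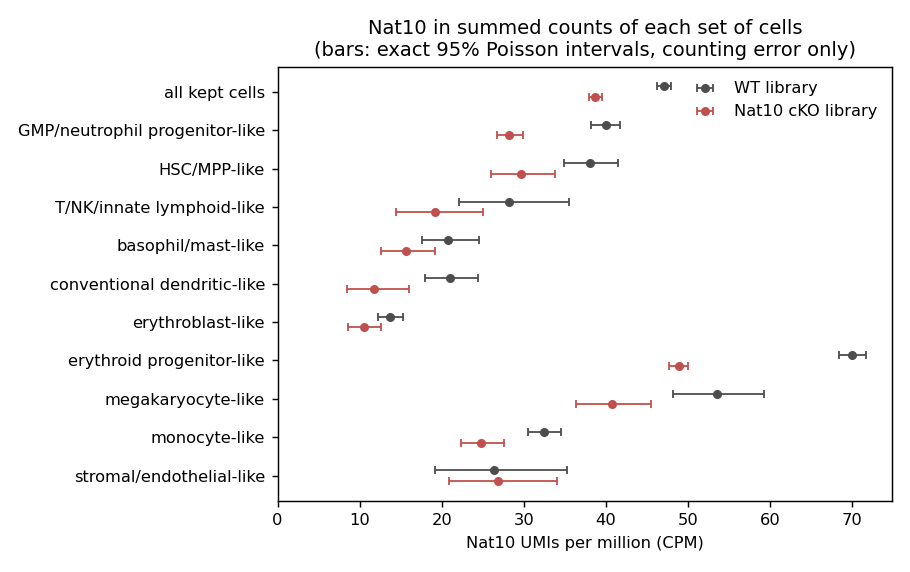
Nat10 level (horizontal axis, CPM) in the summed counts of all kept cells and of each cell class, for the WT library (grey) and the Nat10 cKO library (red), with exact 95% Poisson intervals of counting error. The cKO values lay below the WT values in all sets but the stromal/endothelial-like cells, at 26.4 and 26.8 CPM.

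Stem and progenitor classes held unlike shares of the 2 libraries. HSC/MPP-like cells, which hold the stem cells and the earliest progenitors, made up 5.05% of WT cells (600 of 11870; exact 95% interval 4.67 to 5.46%) and 2.65% of cKO cells (281 of 10621; 2.35 to 2.97%). Their share was thus lower in the cKO library, at a ratio of 0.523 (0.453 to 0.604). Erythroid progenitor-like cells made up 20.4% (19.7 to 21.1%) of WT and 34.4% (33.5 to 35.4%) of cKO cells, a ratio of 1.69 (1.60 to 1.78), while the later erythroblast-like cells stood at 8.39% and 5.86%. Lymphoid progenitor-like cells stood at 1.31% and 0.659%, a ratio of 0.501 (0.373 to 0.669). Monocyte-like cells stood at 8.36% and 4.93%, a ratio of 0.590 (0.530 to 0.657). Granulocyte-monocyte and neutrophil progenitor-like (GMP-like) cells had nearly the same share in both libraries, 11.8% and 12.7%, a ratio of 1.08 (0.999 to 1.16) whose side of 1 changed with the clustering. Megakaryocyte-like cells stood at 2.51% and 3.11%, with a ratio of 1.24 (1.05 to 1.45).

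Smaller classes, most of them mature cells that lineage depletion removes in part, differed as well. Conventional dendritic-like cells had a share ratio of 0.475, plasmacytoid dendritic-like cells 0.269, eosinophil-like cells 0.253 and macrophage-like cells 0.120, all lower in the cKO library. Plasma-like cells had a ratio of 1.98, stromal/endothelial-like cells 1.78 and T, NK and innate lymphoid-like (T/NK-like) cells 1.57. Pro-B and pre-B-like cells numbered 13 in the WT and 141 in the cKO library, a ratio of 12.1 (6.86 to 23.3). Basophil and mast-like cells gave 1.06 and neutrophil-like cells 1.08, both with intervals that held 1. Other clusterings moved several of these ratios by over 1.5 times, to 0.765 for plasmacytoid dendritic-like, 0.541 for eosinophil-like, 1.21 for plasma-like, 3.47 for pro-B and pre-B-like and 0.479 for neutrophil-like cells, and class by marker score gave 0.779 for lymphoid progenitor-like cells. The macrophage-like ratio ranged from 0.0728 to 0.207 over the alternatives. How far depletion went in each preparation was not measured here. Within the progenitor classes alone, HSC/MPP-like cells held 9.35% of WT and 4.17% of cKO cells, and erythroid progenitor-like cells 37.8% and 54.3%. Clusters without a name held 23.6% of WT and 16.5% of cKO cells.

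**Figure D2:**
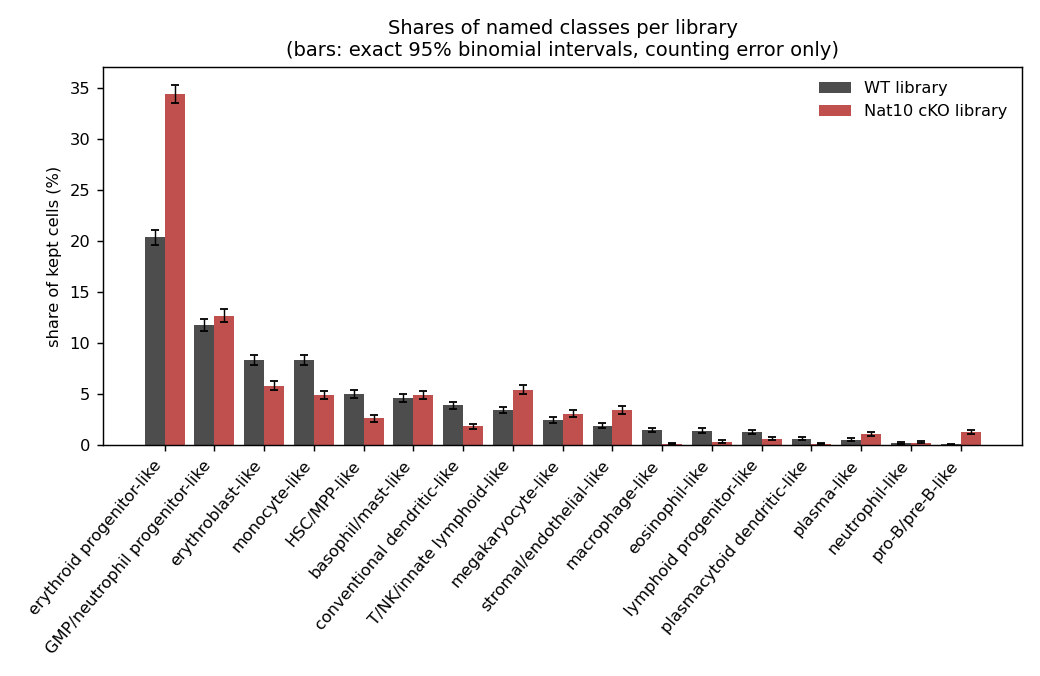
Share of kept cells (vertical axis, percent) in each named class for the WT library (grey) and the Nat10 cKO library (red), with exact 95% binomial intervals of counting error. HSC/MPP-like cells stood at 5.05% and 2.65%, and erythroid progenitor-like cells at 20.4% and 34.4%.

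Cells with UMIs of stem cell genes were also counted without clusters, a measure that falls with fewer such cells and with lower levels of these genes per cell alike. After every cell was thinned to 2000 UMIs, 426 of 9621 WT cells (4.43%; 4.03 to 4.86%) and 230 of 9509 cKO cells (2.42%; 2.12 to 2.75%) held a UMI of at least 2 of 8 stem cell genes, among them Hlf, Mecom and Procr. The ratio was 0.546 (0.463 to 0.643), and it was 0.298 when at least 3 genes were required. Thinning left out 2249 shallower WT cells and 1112 cKO cells, and without it the ratio was 0.803, with a cKO share of 17.7%. The background, measured in erythroblast-like cells that should lack these genes, was 0.664% and 0.575%, at median depths of 24337 and 20232 UMIs before thinning. Of the neutrophil-like cells, 1 of 31 in the WT library and 0 of 30 in the cKO library were positive. In erythroid progenitor-like cells the thinned share was 0.495% in the WT and 0.345% in the cKO library. Without thinning the background was 8.13% and 4.34% in erythroblast-like cells and 16.5% and 12.6% in erythroid progenitor-like cells. The unthinned shares thus hold much background, which was also lower in the cKO library. Within the HSC/MPP-like class itself, 35.0% of WT and 19.6% of cKO cells were positive, against 51.8% and 40.4% at 4000 UMIs and 85% and 82.6% without thinning.

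In HSC/MPP-like cells, stem cell regulators and signal-response genes were lower in the cKO library, and genes of the cell cycle, the mitochondrial ribosome and oxidative phosphorylation were higher. Hlf, a transcription factor of stem cells, stood at 239 CPM in the WT and 120 CPM in the cKO library, a log2 ratio of −0.99 (−1.09 to −0.88). Mecom had a ratio of −0.42 (−0.68 when every cell weighed alike), Procr −0.69, Kit −0.58 and Flt3 −0.39. Hlf and Mecom lead a cluster of this class, as Flt3 does, so these ratios describe cells chosen in part by those genes. The 10 lowest genes included Egr1 at −2.27 (135 against 28.0 CPM) and Nr4a1 at −1.84, both transcription factors switched on within minutes of a stimulus, and Klf2 at −2.10, a factor linked to cell quiescence. The others were Ly6c2 at −2.37, Trpc6 at −2.24, Klf12 at −2.20, Creb5 at −1.87, Rnf217 at −1.85, Skil at −1.82 and Eya2 at −1.81. Ly6c2, a monocyte marker, was also among the lowest genes of erythroblast-like, megakaryocyte-like and stromal/endothelial-like cells, and Klf2 among those of basophil and mast-like cells. These 2 genes are thus not particular to HSC/MPP-like cells, and whether free RNA from other cells adds to their ratios was not tested. Of the 10 highest genes, 5 encode histones: H2ac24 at 1.03, H2ac8 at 307 against 618 CPM, H1f5 at 0.97, H2bc11 at 0.96 and H2ac22 at 0.90. Cyclin D1, encoded by Ccnd1, was highest, at 1.29 (1.05 to 1.54), followed by Gem, at 17.5 against 40.1 CPM, with Cpa3 at 0.93, Unc119 at 0.89 and Rpa3 at 0.87 further down. Scaling by TMM has an offset of −0.13 in these cells, so a log2 ratio of −0.13 lay level with the bulk of the genes. The TMM offset was −0.11 in both erythroid progenitor-like and GMP-like cells, and the median-of-ratios offset was −0.15 in megakaryocyte-like cells.

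**Figure D3:**
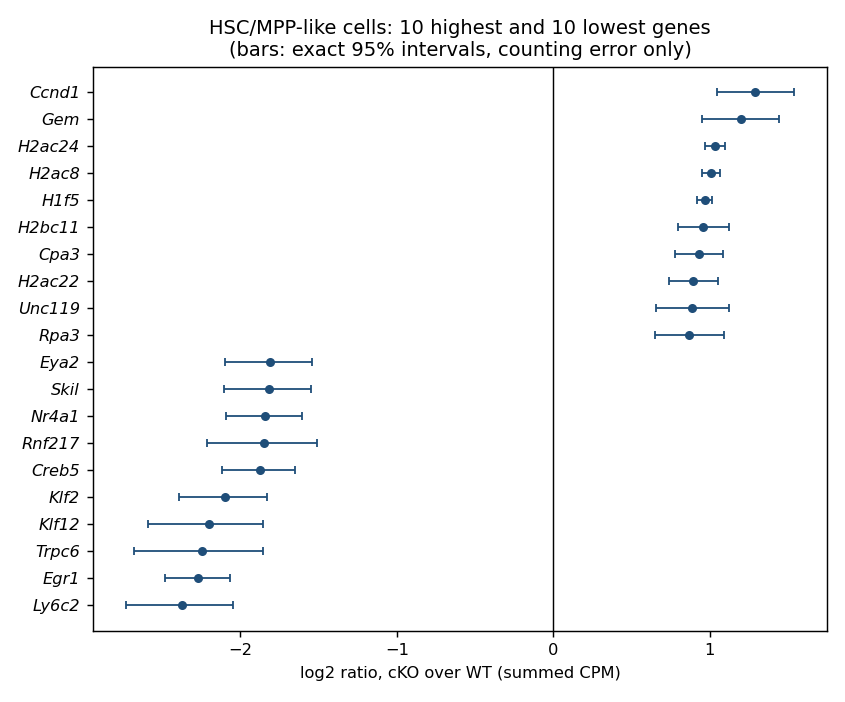
Log2 ratio of the cKO over the WT library (horizontal axis) for the 10 highest and the 10 lowest ranked genes in the summed counts of HSC/MPP-like cells, with exact 95% intervals of counting error. Histone genes and Ccnd1 stood at the high end, and Ly6c2 at −2.37 and Egr1 at −2.27 at the low end.

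Single lineage regulators were also followed in the HSC/MPP-like cells. The erythroid factors Klf1, at 0.80 (0.38 to 1.21), and Gata1, at 0.49 (0.04 to 0.92), were higher in the cKO library at low levels of 7.22 against 12.5 CPM and 7.36 against 10.3 CPM, and the Klf1 ratio became 0.06 when called doublets were kept. Gata2 stood at −0.26, the myeloid factors Cebpa at −0.27 and Spi1 at −0.23 (−0.10 with TMM scaling), and the granule gene Mpo at −0.56. Pf4 at 0.17, Ebf1 at −0.27 and Il7r at −0.51 had intervals that held 0, and Il7r became 0.79 when every cell weighed alike. The p53 gene Trp53 stood at 0.16 (0.29 with TMM scaling), its targets Cdkn1a at −0.67, Mdm2 at −0.37 and Ccng1 at −0.25, Myc at 0.16 and the proliferation marker Mki67 at 0.18 (0.03 with doublets kept).

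Groups of genes lower together in the cKO HSC/MPP-like cells were those of interferon, immediate early and inflammatory responses and those linked to stem cells. Of 30 measured interferon response genes, which respond to virus-sensing and interferon signals, 28 were lower, with a median log2 ratio of −0.80 (−0.94 to −0.67). Ifi27l2a stood at −1.94 and Rsad2 at −1.69, with Ifi47 at 0.39 the highest. Summed over the list, the levels were 883 CPM in the WT and 681 CPM in the cKO library. Of 20 immediate early and heat shock genes, 15 were lower, with a median of −0.69, though the chaperone gene Hsph1 stood at 0.69. Both medians lay below those of all 10000 random lists, whether matched on mean CPM alone or on CPM and gene span. Of 16 inflammatory NF-kB targets, 14 were lower, among them Cxcl10 at −1.27 and Birc3 at −0.94, with a median of −0.50 at percentile 0.1 and, matched on span too, 0.01; at Leiden resolution 2.5 it was −0.33. Of 31 stem cell-associated (HSC-associated) genes, 28 were lower, with a median of −0.43 at percentile 0.01 and, with span, 0.495. The span-matched lists themselves had a median of −0.25, so only −0.18 lay beyond genes of like level and span. Some members, such as Hlf and Mecom, are also markers by which the class was named. Egr1, the lowest member of that list, also belongs to the immediate early list.

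Genes of growth and respiration were higher together in the same cells. Of 44 mitochondrial ribosomal protein genes 43 were higher, led by Mrpl12 and Mrps7, both at 0.69, with a median of 0.46. Of 72 oxidative phosphorylation genes 70 were higher, led by Cyc1 at 0.72 and Sdhd at 0.65, again with a median of 0.46. All 35 MYC targets were higher, with a median of 0.41 and with Ldha at 0.70 and Phb at 0.65. These 3 lists lay at percentile 100 on CPM, and at 100, 100 and 99.4 with span, where the random lists themselves had medians of 0.22, 0.30 and 0.27. The median of 42 ribosome biogenesis genes was 0.24, at percentile 100 on CPM but just within the central range of random lists with span, whose median was 0.13, with Nhp2 at 0.70 and Ebna1bp2 at 0.63. The 12 measured genes encoded in the mitochondrial genome did not share this direction: 9 were lower, mt-Atp8 stood at −0.51, and their median of −0.09 turned to 0.04 under TMM scaling.

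Cell cycle genes were higher as well. Of 52 G2/M genes 45 were higher, with a median of 0.24 and with Ube2c at 0.69 and Tubb4b at 0.68. Of 43 S phase genes 39 were higher, with a median of 0.23 and with Rrm2 at 0.75 and Tyms at 0.73. Percentiles on CPM and span were 100 for the G2/M and 99.9 for the S phase genes. At Leiden resolution 2.5 the medians were 0.14 and 0.10, and with TMM scaling both were 0.36.

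Other parts of the translation machinery were higher without standing apart from genes of like level and span. All 79 cytosolic ribosomal protein genes were higher, with a median of 0.32 at percentile 92.2 on CPM and 33.6 with span, and with Rplp0 at 0.61. The random lists could draw these genes themselves, so their percentiles cannot tell whether the list stands apart. The 37 translation factors had a median of 0.19, at percentiles 97.7 and 44.7, with Eif5a at 0.71 and Eif6 at 0.61. Glycolysis genes had a median of 0.15 and a span percentile of 90.9. With TMM scaling the medians were 0.32 for translation factors, 0.28 for glycolysis and 0.37 for ribosome biogenesis.

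Stress and death programmes lay within the range of random lists. Of 27 p53 targets 20 were lower, with a median of −0.21 at percentile 23.0 on CPM and 9.08 with span, and with Plk2 at −1.26 and Bax at 0.58. The integrated stress response had a median of 0.04 (span percentile 66.1), the unfolded protein response 0.04 (47.6), the apoptosis regulators −0.11 (41.8) and cholesterol biosynthesis −0.19 (18.2). TMM scaling gave −0.08 for the p53 targets and 0.17 for the unfolded protein response, which was 0.30 with genes scaled within each library, and a floor of 500 UMIs gave −0.33 for cholesterol biosynthesis.

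Lists of lineage genes were followed in the HSC/MPP-like cells as well. Erythroid genes had a median of 0.12 at percentile 99.1 on CPM and 87.6 with span, which turned to −0.45 when called doublets were kept and was 0.00097 when every cell weighed alike. Megakaryocyte genes, with a median of −0.37 at percentiles 4.28 and 13.7, lay within the range of random lists. So did lymphoid genes, with −0.36 at percentiles 4.10 and 7.99, with Lax1 at −2.37 and Foxo1 at −1.54. MHC class II genes had −0.47 over 5 members, at percentiles 8.15 and 2.46, and −1.02 without the floor on counts. Myeloid granule genes had −0.33, at percentiles 5.57 and 0.03, and −0.07 with genes scaled within each library. Mpo was also lower in erythroid progenitor-like cells, which should not make it, at 140 CPM in the WT and 85.2 CPM in the cKO library.

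**Figure D4:**
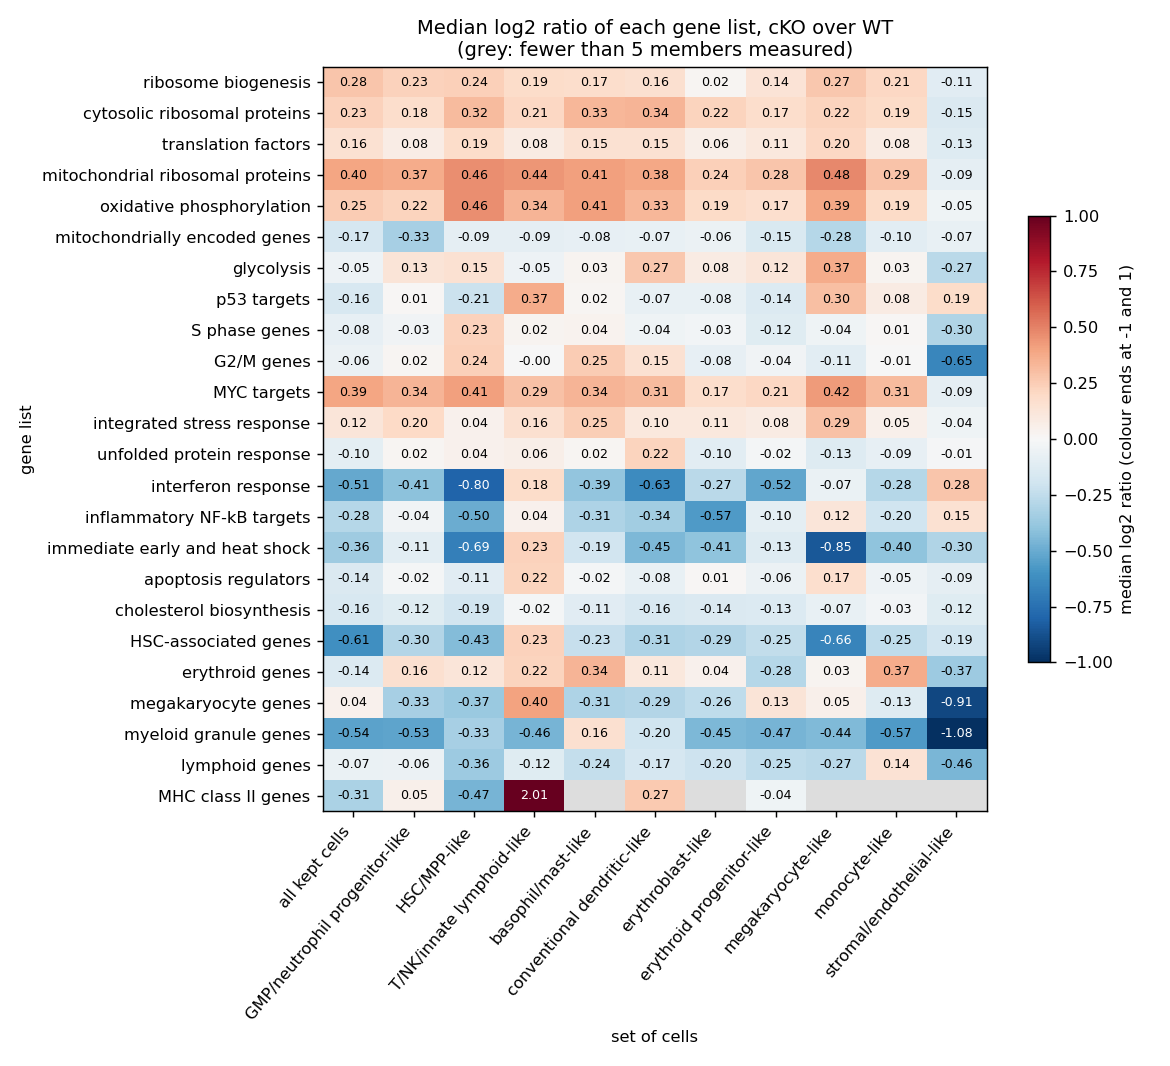
Median log2 ratio of the cKO over the WT library for each gene list (vertical axis) in all kept cells and each class (horizontal axis), as colour and number. Interferon response genes stood at −0.80 and mitochondrial ribosomal protein genes at 0.46 in HSC/MPP-like cells. The HSC/MPP-like median of −0.09 for genes encoded in mitochondria and the erythroid progenitor-like G2/M median of −0.04 turn positive under TMM scaling.

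Long genes were lower and short genes higher in the cKO library in every class but the stromal/endothelial-like cells. In HSC/MPP-like cells, genes that span under 3 kb had a median log2 ratio of 0.30 and genes over 300 kb one of −0.48. Across genes, which are not independent replicates, Spearman's rho between span and ratio was −0.58 in HSC/MPP-like and GMP-like cells, −0.59 in erythroid progenitor-like cells, −0.35 in T/NK-like cells and 0.07 in stromal/endothelial-like cells. Mitochondrial ribosomal protein genes lay at percentile 100 with span in all 10 classes but the stromal/endothelial-like cells, where their median was −0.09 (10.9) and turned to 0.32 with the WT mix of clusters but was −0.15 with the stricter filter.

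**Figure D5:**
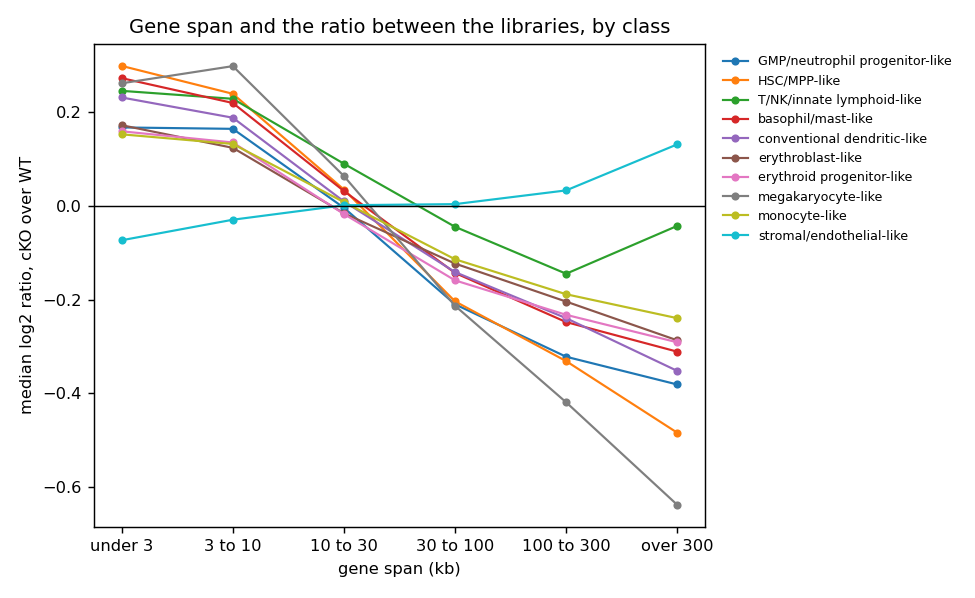
Median log2 ratio of the cKO over the WT library (vertical axis) of ranked genes in 6 bins of gene span (horizontal axis, kb), with 1 line per class. In HSC/MPP-like cells the median went from 0.30 under 3 kb to −0.48 over 300 kb, while the stromal/endothelial-like cells went the other way.

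In erythroid progenitor-like cells, the branch with the higher cKO share, genes of red cell differentiation and of the interferon response were lower in the cKO library. Of 22 erythroid genes 16 were lower, with a median of −0.28 (−0.31 to −0.27) at percentile 0, or −0.17 with TMM scaling. With the WT mix of clusters this median was −0.05, so most of the fall in red cell genes went with another mix of clusters in the class. Slc4a1, the anion exchanger of the red cell membrane, stood at 51.4 against 23.9 CPM, a log2 ratio of −1.11, and the haemoglobin gene Hbb-bt at −0.71. The master factors did not follow: Klf1 stood at 0.11 (0.04 when every cell weighed alike, 0.22 with median-of-ratios scaling) and Gata1 at 0.01, while Gata2, which acts earlier, stood at 0.40. Interferon response genes had a median of −0.52, at percentile 0, with Ifi27l2a at −2.16 and Ifi44 at −1.75. Of 43 S phase genes 35 were lower, with a median of −0.12 (percentile 11.8 on CPM, within the range of random lists, and 0.06 with span) and with Dtl at −0.54 and Pola1 at −0.40. Mki67 stood at −0.28, and under TMM scaling Gata1 was 0.12, the S phase median was −0.01 and the G2/M median of −0.04 turned to 0.07. Mitochondrial ribosomal protein genes were higher, with a median of 0.28 and with Mrpl11 and Mrpl17 at 0.39. MYC targets stood at 0.21, with Ldha at 0.49 and Srm at 0.38, and oxidative phosphorylation genes at 0.17, at a span percentile of 78.6; TMM scaling gave 0.32 and 0.28.

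The ranked ends of this class were Pcdh7 at 0.94, Pusl1 at 0.80, Ppm1e at 0.79, the ubiquitin gene Ubb at 0.66 and Ydjc at 0.66, against Gpc4 at −1.33, Eda at −1.13, Pdgfd at −1.07 and Hipk2 at −1.05. Myeloid granule genes had a median of −0.47 in these cells, with Mpo at −0.72. One of the class's clusters, led by C1qtnf12, Mt2 and Sphk1, held 178 WT and 799 cKO cells. With the cKO clusters reweighted to their WT shares, the erythroid median was −0.05 in place of −0.28, with Slc4a1 at −0.48, Hbb-bt at −0.22, Gata2 at 0.22, Srm at 0.22, Ydjc at 0.44, Hipk2 at −0.68, Pola1 at −0.26 and Mki67 at −0.09. In erythroblast-like cells the erythroid median was 0.04 (−0.06 with the stricter filter), the mitochondrial ribosomal protein median 0.24 and the interferon median −0.27, or −0.09 when every cell weighed alike. The histone gene H4c17 stood highest there at 1.03, with the metallothionein genes Mt1 at 0.90 and Mt2 at 0.83 and with Ppm1e at 0.90, beside Slfn14, which leads a cluster. Eda was lowest at −1.10, with Ly6c2 at −1.08, Tnfrsf21 at −0.99, Chst10 at −0.92 and Gab2 at −0.89.

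In GMP-like and monocyte-like cells, genes of neutrophil and monocyte granules were lower in the cKO library. In GMP-like cells, 14 of 17 myeloid granule genes were lower, with a median of −0.53 at percentile 0, and S100a8 stood at −1.61 and Mpo at −0.62, while Lcn2 stood at 0.59. In monocyte-like cells the same list had a median of −0.57, at percentile 0, with Elane at −1.57 and Mpo at −0.98. With the WT mix of clusters these medians were −0.18 in GMP-like and −0.25 in monocyte-like cells, and S100a8 in GMP-like cells was −1.02. A GMP-like cluster led by Elane and Wfdc21 held 599 WT and 380 cKO cells, and another led by Prtn3 and Elane held 299 and 585. Basophil and mast-like cells did not share this, with a granule median of 0.16 and summed levels of 4358 CPM in WT and 4400 CPM in cKO cells. Conventional dendritic-like cells had a median of −0.20 but nearly level sums of 1852 and 1811 CPM. Granule genes were lower outside the myeloid cells too: their summed level was 401 CPM in WT and 284 CPM in cKO erythroid progenitor-like cells, and 2269 and 1012 CPM in stromal/endothelial-like cells. The myeloid factor Cebpa stood at −0.20 in GMP-like (−0.08 with TMM scaling) and −0.33 in monocyte-like cells, and Spi1 at −0.09 in GMP-like cells, which turned to 0.02 under TMM scaling.

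Interferon and growth genes were followed in the same myeloid classes. Interferon genes had a median of −0.41 in GMP-like cells, with Ddx58 at −1.31 and Ifi27l2a at −1.08. Summed over the list, GMP-like cells were nearly level, at 480 CPM in the WT and 476 CPM in the cKO library. In monocyte-like cells the interferon median was −0.28, which became −0.09 with the WT mix of clusters and −0.45 at Leiden resolution 2.5. Immediate early genes had a median of −0.11 in GMP-like cells, at percentile 54.1 on CPM and 0.87 with span, where NF-kB targets stood at −0.04, and one of −0.40 in monocyte-like cells, with Egr1 at −1.31 and Fosb at −1.15, though Hspa1a stood at 0.66. In GMP-like cells, mitochondrial ribosomal protein genes had a median of 0.37, led by Mrps6 at 0.63 and Mrpl12 at 0.60, and MYC targets one of 0.34, led by Hspd1 at 0.59 and Prmt1 at 0.56. HSC-associated genes had a median of −0.30 there (−0.18 with TMM scaling), within the range of random lists with span at percentile 19.2, with Hlf at −0.99 and Egr1 at −1.19. The highest GMP-like genes were Hmga2 at 1.19, Prdx4 at 1.12, Ctla2a at 0.88, Fabp5 at 0.85 and Pusl1 at 0.85, and the lowest, apart from the granule gene Fcnb that leads a cluster, were the adhesion gene Vcam1 at −2.72, Clec4a2 at −2.07, Aff2 at −2.06 and Ncam1 at −1.86. In monocyte-like cells, Cnn3 at 1.16, Egfl7 at 1.09 and Blvrb at 0.99 stood high and Rnf217 at −1.89 and Itga1 at −1.65 low. With the WT mix of clusters Cnn3 was 0.67, Egfl7 0.65 and, in GMP-like cells, Prdx4 0.67, and with doublets kept Blvrb was 0.20. The other ranked genes, Ccnd1, Flt3, Nrg1, Ly6a2 and Fn1, lead clusters of the class itself, among them one led by Lyz2 and Fn1 with 221 WT and 42 cKO cells. Erythroid genes had a median of 0.37 in monocyte-like cells, which turned to −0.21 when called doublets were kept.

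In conventional dendritic-like cells the interferon median was −0.63, with all 21 members lower, and the mitochondrial ribosomal protein median 0.38, or 0.09 at Leiden resolution 2.5. At that resolution the class held only 87 WT and 31 cKO cells, in place of 468 and 199, while monocyte-like cells rose from 992 and 524 to 1732 and 784. Its main cluster, with 457 WT and 182 cKO cells, was led by Pid1, Lgals3 and S100a4. Only H2-Aa and Cd74 of the dendritic markers were among its leading genes, and both are also mature B cell markers. The name of this class is therefore uncertain. Cd36 stood at 2.27, P3h2 at 1.98, Plpp1 at 1.84 and Apoe at 1.73, beside Cadm1, which leads a cluster of the class, against Nrg1 at −2.65, the calcium channel gene Cacna1e at −2.20, Tmcc3 at −2.19, the decoy receptor gene Il1r2 at −2.09 and Plcb1 at −1.97. With the WT mix of clusters P3h2 was 0.31 and Plpp1 0.48, and Cd36 was lower by over 1.5 times.

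Megakaryocyte-like cells had stem cell and immediate early genes lower in the cKO library, in a class whose makeup differed. A cluster with Pf4 and Trpc6 among its leading genes held 229 WT and 165 cKO cells, and a platelet-like cluster led by Ppbp, Clu and Pf4 held 69 and 165. The p53 target median was 0.30, at a span percentile of 99.8, but 0.0065 with the WT mix of clusters, with Phlda3 at 4.81 and the cell cycle inhibitor gene Cdkn1a at 2.30 (13.6 against 67.5 CPM), which was also lower by over 1.5 times with that mix. Ccng1 at 0.36 and Mdm2 at 0.30 turned to −0.031 and −0.0034 with the WT mix of clusters. Gata1 stood at 1.30 (0.82 with that mix) and Pf4 at −0.16, which turned to 0.24 when every cell weighed alike and was −0.30 with that mix. HSC-associated genes had a median of −0.66, with Hlf at −2.18, immediate early genes −0.85, with Fosb at −1.74 and Egr1 at −1.70, and mitochondrial ribosomal protein genes 0.48. The interferon median was −0.07, or 0.22 when every cell weighed alike and −0.28 with the WT mix of clusters, with Isg15 at 4.25. The highest genes were Lilrb4b, with 3 WT UMIs and a log2 ratio of 6.92 (5.59 to 9.43), Mest at 6.53 (5.33 to 8.58), D5Ertd615e at 5.91, Frmd5 at 4.91 and Rhoc at 4.28. Besides Hlf, the lowest were Il6ra at −2.42, Airn at −1.98, Cadps2 at −1.94 and Ly6c2 at −1.82.

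In T/NK-like cells, p53 targets and MHC class II genes were higher in the cKO library. The p53 median was 0.37, at a span percentile of 99.8, with Cdkn1a at 1.71 and Ccng1 at 0.88 but Mdm2 at −0.24. All 5 measured MHC class II genes, which antigen-presenting cells make, were higher, with a median of 2.01 and Cd74 at 2.46. A cluster led by Inpp4b, Il2ra, Gata3 and Il7r held 90 WT and 238 cKO cells. The interferon median of 0.18 and the immediate early median of 0.23 were positive, and the latter turned to −0.38 with the WT mix of clusters. Serpine2 at 3.53, Cntn1 at 3.00, Fam184b at 2.80 and Cfap53 at 2.68 stood highest, and Dgkh at −1.57, Kifc3 at −1.55, Ifngas1 at −1.55, Cmah at −1.54 and Klra6 at −1.52 lowest. With the WT mix of clusters these 5 were −0.72, −0.83, −0.42, −0.43 and −0.36.

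Basophil and mast-like cells had an interferon median of −0.39, a G2/M median of 0.25 and a mitochondrial ribosomal protein median of 0.41. Pcdh7 stood at 1.15, against Mir99ahg at −1.99, Kif26b at −1.57, St8sia6 at −1.55, Klf2 at −1.50 and the prostaglandin synthase gene Ptgs2 at −1.30. The other high genes, Tpsb2, Mcpt4, Cma1 and Hs6st2, lead a mast cell cluster of 21 WT and 34 cKO cells. In stromal/endothelial-like cells the bone matrix gene Spp1 stood at 4.14 (61.5 against 1086 CPM), Sox2ot at 5.65 (3.72 to 11.54, from 1 WT UMI), Tmem232 at 4.29 (2.92 to 6.81, from 3 WT UMIs) and Anks1b at 3.63. Myo3b had 0 UMIs in the WT library, which allows up to 2.16 CPM, and 48.5 CPM in the cKO library. The lowest were F13a1 at −2.50, Sox6 at −2.42, Ly6c2 at −2.28, S100a8 at −2.23 and Tyrobp at −2.09, and the myeloid granule median was −1.08. With doublets kept that median was −0.018, and F13a1 was −1.33, Sox6 −1.43, Ly6c2 −1.05 and Tyrobp −1.14, while the stricter filter gave −0.47 for S100a8. When every cell weighed alike, S100a8 was −4.46, Spp1 2.70, Sox2ot 3.69, Tmem232 1.90 and Anks1b 1.70. One stromal cluster, led by Pdzrn4, Csmd1 and Ghr, held 79 WT and 197 cKO cells.

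Over all kept cells, many of the ranked genes belong to classes of unlike share in the 2 libraries. Stromal genes Ibsp at 1.55, Pdzrn4 at 1.54, Cxcl12 at 1.07 and Ghr at 0.91, the plasma cell gene Jchain at 1.10, the B cell factor Ebf1 at 1.06 and the neutrophil gene Camp at 0.85 stood high, with Mcrip2 at 0.86, Tjp1 at 0.85 and Mt1 at 0.81. Monocyte and macrophage genes stood low, with Nrg1 at −2.82, Ly6a2 at −2.23, Vcam1 at −1.81, Mpeg1 at −1.63, Klf4 at −1.59 and Ly6c2 at −1.51, beside Klf2 at −1.79, Mir99ahg at −1.68, Plcb1 at −1.60 and Pid1 at −1.57. Hlf stood at −1.44, Mpo at −0.94, Klf1 at 0.39 and Gata1 at 0.33. With the WT class shares Ebf1 was 0.03, Klf1 and Gata1 0.08, Jchain and Ghr 0.34, Cxcl12 and Mt1 0.51, Pdzrn4 0.92 and Ibsp 0.94. When every cell weighed alike, Ebf1 was 1.94 and Klf2 −1.16. Among the low genes, with the WT class shares, Pid1 was −0.65, Mpeg1 −0.67, Klf4 −0.81, Hlf −0.82 and Vcam1 −1.07. Of the sex-linked genes, Xist stood at 905 CPM in the WT and 650 CPM in the cKO library, a log2 ratio of −0.48, and its antisense gene Tsix at −0.56 (−0.36 with the WT class shares). The Y-linked gene Ddx3y stood at 2.83 and 3.38 CPM, a log2 ratio of 0.26 (0.03 when every cell weighed alike). In HSC/MPP-like cells Xist stood at −0.62 and Tsix at −0.67.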

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

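The tests of gene span, of the cluster mix, of free RNA member by member and of the class shares were chosen after the result was seen; that of summed free RNA was fixed before.

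Gene groups were flagged where their highest and lowest class medians pointed opposite ways and both lay at the ends of random lists matched on CPM. These differences between classes were not tested. Lists that missed this rule could also point opposite ways, such as MHC class II genes (2.01 in T/NK-like, −0.47 in HSC/MPP-like cells). Interferon genes were another, at 0.28 in stromal/endothelial-like and −0.80 in HSC/MPP-like cells. Cytosolic ribosomal protein genes differed by 0.49 between conventional dendritic-like cells (0.34) and stromal/endothelial-like cells (−0.15). Glycolysis genes differed by 0.64 between megakaryocyte-like (0.37) and stromal/endothelial-like cells (−0.27), and S phase genes by 0.53 between HSC/MPP-like (0.23) and stromal/endothelial-like cells (−0.30). G2/M genes differed by 0.90 between basophil and mast-like (0.25) and stromal/endothelial-like cells (−0.65). Erythroid genes differed by 0.74 between monocyte-like (0.37) and stromal/endothelial-like cells (−0.37), and megakaryocyte genes by 1.31 between T/NK-like (0.40) and stromal/endothelial-like cells (−0.91). Immediate early and heat shock genes differed by 1.08 between T/NK-like (0.23) and megakaryocyte-like cells (−0.85). Among lists matched on span too, the T/NK-like immediate early median lay at percentile 86.1. The stromal/endothelial-like cytosolic ribosomal protein median lay at 11.2, so both were within the central range of random lists, and the other ends of these groups were outside it.

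Stromal/endothelial-like cells stood at the low end of 6 of these 7 groups. With the WT mix of clusters their medians became 0.32 for cytosolic ribosomal proteins, 0.09 for glycolysis, 0.15 for S phase, 0.14 for erythroid and −0.14 for G2/M genes. Other alternatives moved medians the other way, among them glycolysis to −0.49 with the stricter filter and S phase to −0.58 when every cell weighed alike. At their lowest over the alternatives, the G2/M median was −0.97 and the cytosolic ribosomal protein median −0.22. At the other ends, the megakaryocyte-like glycolysis median was 0.12 when every cell weighed alike, and the T/NK-like median of megakaryocyte genes was 0.09 with genes scaled within each library. With doublets kept, the erythroid medians of monocyte-like and stromal/endothelial-like cells no longer pointed opposite ways, at −0.21 and −0.18. The T/NK-like immediate early median became −0.38 with the WT mix of clusters, and the stromal/endothelial-like median of megakaryocyte genes turned to 0.33 at Leiden resolution 2.5. Barcodes over the mitochondrial limit, left out of the comparisons except where all barcodes were used, made up 7.92% of the cKO barcodes (1067 of 13479; 7.47 to 8.38%) and 4.63% of the WT barcodes (733 of 15848; 4.30 to 4.96%).

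The growth and respiration genes that were higher in cKO HSC/MPP-like cells fall into 2 parts. Translation factors and cytosolic ribosomal proteins did not stand apart from span-matched lists, where the higher of their percentiles was 44.7. Those lists could draw a list's own members, which weighs most for the short and abundant ribosomal protein genes. Span thus stays open for both lists, and this test cannot settle it for the ribosomal proteins. Mitochondrial ribosomal protein, oxidative phosphorylation and MYC target genes lay beyond span-matched lists, at a lowest percentile of 99.4, which argues against span as their whole cause. Their medians exceeded those of span-matched lists, which were 0.22, 0.30 and 0.27, by 0.25, 0.17 and 0.15. Span may account for the rest, which was the larger part for oxidative phosphorylation and MYC targets. These lists were judged by percentile alone, whereas the interferon and immediate early lists below also had to pass a limit on the size of the difference. Ribosome biogenesis genes lay just within the range of span-matched lists, 0.11 above their median. Another mix of cells within the class stays open: its 2 clusters held 86.5% and 13.5% of the WT and 83.6% and 16.4% of the cKO cells, so reweighting, which left at least 0.998 of each median, could move little. A difference by genotype stays open as a hypothesis, and with 1 library each it is confounded with library preparation.

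Interferon and immediate early genes were lower in cKO HSC/MPP-like cells beyond what span gives, by −0.69 and −0.92 against span-matched lists. Reweighting to the WT clusters left 0.962 and 0.994 of the medians, which decides nothing for the same reason. For free RNA from other cells, the summed difference was 0.528 and 0.595 of the lowest WT sum in any class, which decides nothing. Member by member, free RNA allowed drops of −0.36 and −0.18, or 0.452 and 0.256 of those seen, so it may hold a part but not the whole. Handling of the cells, which can induce immediate early genes, cannot be told apart from genotype with 1 library each, and a biological difference stays open as well.

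The lower HSC/MPP-like and higher erythroid progenitor-like shares kept their directions in the tests run. With other cell filters the highest HSC/MPP-like ratio was 0.552 and the lowest erythroid ratio 1.58, and with other clusterings they were 0.714 and 1.55. The filters were changed without clustering again: kept cells held their class, and added barcodes took the nearest class. HSC/MPP-like counts thus changed little, from 578 to 639 in the WT and from 275 to 300 in the cKO library. Dilution by more erythroid cells would lower all other classes alike. Only the 8 other classes with at least 100 cells in both libraries were compared. Of these, 4 had ratios above the HSC/MPP-like one, beyond counting error, under each of these filters and clusterings: T/NK-like, stromal/endothelial-like, basophil and mast-like and megakaryocyte-like cells. The smaller classes left out had ratios from 0.120 (macrophage-like) to 12.1 (pro-B and pre-B-like), with lymphoid progenitor-like cells at 0.501. The HSC/MPP-like ratio was at most 0.454 of the T/NK-like and 0.675 of the megakaryocyte-like ratio. Against GMP-like cells it was 0.486 (0.414 to 0.570) with the clusters used, but 0.847 with genes scaled within each library, where the interval reached 1, and conventional dendritic-like, monocyte-like and erythroblast-like cells were not apart from it in every setting. These values argue against the clustering settings run and dilution as the whole cause. For the filters they speak only to which cells were counted, not to how a filter shapes the clusters. Every setting, however, named HSC/MPP-like cells by the same marker list, whose members Hlf and Mecom were lower in the cKO cells of the class. That cKO cells left the class through lower markers therefore stays open. With genes scaled within each library the HSC/MPP-like share ratio was 0.697. The depth of lineage depletion in each preparation, which was not measured, and a difference by genotype both stay open.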

How the results depend on the processing

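The named-class denominator and reweighting to WT cluster shares were chosen after the result was seen; the other alternatives were planned. No paired analysis was possible because there was 1 library per genotype, and leaving out a replicate was not possible for the same reason. Over the alternatives run, the share ratio stayed below 1 for HSC/MPP-like (0.446 to 0.714), lymphoid progenitor-like (0.428 to 0.779) and monocyte-like cells (0.503 to 0.856) and above 1 for erythroid progenitor-like (1.44 to 1.82) and megakaryocyte-like cells (1.03 to 1.55). It crossed 1 for GMP-like (0.823 to 1.11), basophil and mast-like (0.904 to 1.19) and neutrophil-like cells (0.479 to 1.14). In the counts that follow, a value turned only if its sign changed and its main counting interval left out no difference. A change of sign where that interval held no difference counts as moved, or as unchanged if the new value lay inside it. Of the principal list medians, 44 values stayed within their counting intervals, 26 moved and 0 turned. For other list medians these counts were 716, 233 and 18, and for single genes 1642, 457 and 7. Depth limits the small classes most: Nat10 in stromal/endothelial-like cells had an interval from −0.54 to 0.60. Where the construction of an alternative does not show it, the cause was not tested.

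For class shares other than the principal ones, 85 values stayed within their counting intervals, 15 moved and 0 turned by the same rule. Basophil and mast-like and neutrophil-like ratios, whose intervals allowed equal shares, changed side without counting as turned. The principal class share ratios that moved were as follows. The stricter filter gave 0.995 for GMP-like, 1.58 for erythroid progenitor-like, 1.03 for megakaryocyte-like and 0.517 for monocyte-like cells, and all barcodes gave 1.81 for erythroid progenitor-like and 1.55 for megakaryocyte-like cells. Genes scaled within each library gave 0.823 for GMP-like, 0.697 for HSC/MPP-like, 1.55 for erythroid progenitor-like, 1.03 for megakaryocyte-like and 0.856 for monocyte-like cells. Marker scores gave 0.844 for GMP-like, 1.82 for erythroid progenitor-like and 0.779 for lymphoid progenitor-like cells. Named classes alone as denominator gave 0.985 for GMP-like and 1.54 for erythroid progenitor-like cells. Progenitor classes alone gave 0.919 for GMP-like, 0.446 for HSC/MPP-like, 1.44 for erythroid progenitor-like and 0.503 for monocyte-like cells. Resolution 0.8 gave 0.714 for HSC/MPP-like cells, and resolution 2.5 gave 0.685 for them and 0.506 for monocyte-like cells. Without cell cycle, ribosomal protein and mitochondrial genes, erythroid progenitor-like cells gave 1.79 and monocyte-like cells 0.679. The HSC gene-positive ratio was 0.298 with 3 genes, 0.803 without thinning and 0.673 at 4000 UMIs.

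Nat10 in all kept cells was −0.19 with TMM, −0.21 with median-of-ratios factors, −0.34 with mean per-cell CPM, −0.23 with reduced totals and −0.45 at WT class shares. In erythroid progenitor-like cells it was −0.41 with both factors and −0.59 at WT cluster shares, and in erythroblast-like cells 0.058 with mean per-cell CPM. Other genes that turned by the rule above were Spi1 in GMP-like cells (0.020 with TMM, 0.0080 with median-of-ratios), Slfn14 in erythroblast-like cells (−0.48, stricter filter) and Pf4 in megakaryocyte-like cells (0.24, mean per-cell CPM). At WT cluster shares Thumpd1 turned to −0.029 in erythroid progenitor-like cells, and Ccng1 to −0.031 and Mdm2 to −0.0034 in megakaryocyte-like cells.

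In HSC/MPP-like cells the oxidative phosphorylation median was 0.59 with TMM, 0.57 with median-of-ratios, 0.54 with mean per-cell CPM, 0.55 with reduced totals, 0.43 with all barcodes or with doublets kept, 0.39 at resolutions 0.8 and 2.5, and 0.53 with genes scaled within libraries. HSC-associated genes gave −0.30, −0.33, −0.53 and −0.35 with the same 4 scalings, −0.61 at resolution 0.8, −0.60 at 2.5 and −0.62 with genes scaled within libraries. Interferon genes gave −0.97 with genes scaled within libraries and −0.56 at the floor of 500 UMIs. Genes encoded in mitochondria turned to 0.038 with TMM and 0.0093 with median-of-ratios, and erythroid genes to −0.45 with all barcodes or doublets kept.

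In erythroid progenitor-like cells interferon genes gave −0.40 with TMM and −0.41 with median-of-ratios. Erythroid genes gave −0.17 with TMM, −0.17 with median-of-ratios, −0.23 with mean per-cell CPM, −0.24 with reduced totals, −0.26 with genes scaled within libraries and −0.052 at WT cluster shares. G2/M genes turned to 0.074 with TMM, 0.068 with median-of-ratios, 0.0083 with reduced totals and 0.013 at WT cluster shares. Erythroid genes in monocyte-like cells turned to −0.22 with all barcodes and −0.21 with doublets kept, and the T/NK-like immediate early median to −0.38 at WT cluster shares. In stromal/endothelial-like cells cytosolic ribosomal proteins turned to 0.013 with all barcodes, 0.016 with doublets kept and 0.32 at WT cluster shares, where glycolysis turned to 0.086, S phase to 0.15 and erythroid genes to 0.14. Their megakaryocyte genes turned to 0.33 at resolution 2.5.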
